A study of Mus musculus and Homo sapiens with 43 samples.

How the data were processed

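The series holds 43 samples, of which 34 are RNA-seq libraries of KSIC_806 mouse pancreatic cancer cells. The other 9, from ChIP-seq and ATAC-seq and including 1 of the human line Panc1, were not analysed here. Per the labels' protocols, cells were plated in 2.5 µM MK2206, an inhibitor of the kinase AKT, before 2.5 µM SB505124 or 100 pM TGFβ was added, and doxycycline was given at 1 µg/mL at plating where indicated. That text covers every sample, D10F included. The arms are named Akt and D10F, and the Akt libraries at 2 h are described as Akti. Columns of the Akt groups at 2 h and 12 h are all headed Akti, and those of D10F are not. Whether the D10F cells had MK2206 is therefore unclear, and what the contrast of Akt and D10F cells measures is unclear with it. The origin of the S4.1 cells is not stated. Libraries were made with the TruSeq RNA kit v2, per the labels' protocols. That kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart, and genes with close paralogs can share reads.

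Per the submitters' processing notes, the tools used were FastQC 0.11.5, Bowtie2, HTSeq 0.6.1p1, DESeq2 3.4 and HOMER, with the builds mm10 and hg19. The notes give neither the role of each tool nor how reads matching several genes were treated. The deposited signal values are gene counts that the authors divided by a size factor per library, in 4 tables that were normalized separately. The columns name group and library, and none was left unused. Columns named A1 were matched to the S4.1 samples through the sample descriptions of the ChIP-seq libraries. Whole reads were recovered from each column: 100% of the values lay within 0.01 of a whole multiple of the column's unit. The recovered totals ran from 27,000,000 to 33,000,000 in the TOId1 table, 12,200,000 to 16,100,000 in the S4 table, 13,500,000 to 16,200,000 in the GFP table and 27,200,000 to 35,200,000 in the Akt table per library. The tables list 16716, 16811, 17119 and 24062 genes in that order.

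The 2 libraries of each group were compared before they were averaged. All 17 pairs differed by more than sampling noise, with chi-square per degree of freedom from 1.69 to 16.3 and Pearson's r on the log2 scale, across genes, of at least 0.990, so each library was counted as 1 replicate. The number given to a library is its column order and names it only.

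Values were put on the log2(normalized count + 1) scale, and genes with a mean of at least 10 over a table's libraries were tested: 11918 in the TOId1 table, 11691 in the S4 table, 11885 in the GFP table and 12362 in the Akt table. Fold changes on this scale understate the change of genes with low counts. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and all libraries of a table in the fit, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The 18 comparisons set TGFβ against SB505124 in each arm, the arms against each other under SB505124, and the responses of paired arms against each other, plus the Akt cells at 2 h and between 2 h and 12 h. The unit matched the design as written, and the tests, gene lists, these comparisons, the alternatives for counts and list tests and the rule for named genes were fixed before the data were examined. For single genes, the alternatives of only the compared groups, edgeR, DESeq2 and left-out libraries were added after the results were seen. Another 3 comparisons, between arms under TGFβ, were added after the results were seen. On the recovered reads, edgeR 4.0.16 called 8091 genes in TOId1 cells without doxycycline and 7830 with it, where limma called 8024 and 7756. DESeq2 1.42.0 called 7398 and 7143.

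Gene lists, 34 in number, were tested with camera at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the data. Lists with fewer than 3 measured members were counted and not tested. The text names the 8 largest changes each way in the 5 reference arms and the 5 largest in other comparisons, among called genes with a mean of at least 100 in the higher group and separated libraries. It also names 14 fixed genes and up to 4 members of a list, and passes over gene models without a name. Some of the genes so chosen are not reported here. Where a group had no read of a gene, a lower bound of the fold was set with a floor of 3 reads over the libraries of the group. Floors cover counting error only. Positions of genes were taken from the RefSeq annotation of GRCm38, the assembly that mm10 names.

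The test was tried on simulated data in which 200 genes were changed. Each gene had the same dispersion in every group, and genes varied independently. Recovery depends on the number of changed genes, which was set at 200 and not matched to each comparison. Changes of 1.5-fold were recovered in 83.6% of changed genes for TOId1 cells without doxycycline and in 13.4% for the difference between the GFP arms, and 2-fold changes in 86.6% and 79.1%. Unchanged genes made up 6.77% and 5.43% of the calls there, and 10.4% for TOId1 cells with doxycycline, the highest share.

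Alternatives were no filter on low counts, a pseudocount of 5, rescaling each library to a common upper quartile, edgeR and DESeq2 on recovered reads, only the compared groups in the fit, and each library left out in turn. Leaving out a library leaves its group with 1, which is then assumed to vary like the other groups.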

Results

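Mouse pancreatic ductal adenocarcinoma cells of the line KSIC_806 were profiled by RNA-seq with TGFβ signalling blocked by SB505124, an inhibitor of the TGFβ receptor kinase, or switched on by 100 pM TGFβ. The series asks how ID1 lets such cells escape the tumour-suppressing arm of this pathway. Id1, Id2 and Id3 encode helix-loop-helix proteins without a DNA-binding region that hold E proteins away from DNA. In mm10 (GRCm38), Id1 lies on chromosome 2 from 152736251 to 152737410, Id2 on chromosome 12 from 25093799 to 25096092, and Id3 on chromosome 4 from 136143822 to 136145392. The 34 RNA-seq libraries formed 17 groups of 2 in 4 tables. The first table held TOId1 cells with or without doxycycline at 24 h. The second held the S4 and S4.1 cells, with TGFβ for 1.5 h and SB505124 for 4 h. In the third, GFP-negative and GFP-positive cells had TGFβ for 2 h and SB505124 for 4 h. The fourth held cells labelled D10F and cells labelled Akt at 12 h, and the Akt cells also after 2 h of TGFβ. Recovered reads per library numbered 27,000,000 to 33,000,000 in the TOId1 table, 12,200,000 to 16,100,000 in the S4 table, 13,500,000 to 16,200,000 in the GFP table and 27,200,000 to 35,200,000 in the Akt table. Markers of other cell types were scarce in TOId1 cells, where 2 of 12 fibroblast, 2 of 14 leukocyte, 3 of 10 endothelial, 2 of 13 acinar and 0 of 11 endocrine markers reached the minimum mean of 10 normalized counts.

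Changes are log2 fold changes on the log2(normalized count + 1) scale ± SE from limma, with Benjamini-Hochberg adjusted p and 2 libraries per group throughout. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each gene named as changed between 2 groups had both libraries of one group above both of the other. The tables were normalized separately, and tests were made only within a table.

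**Figure D1:**
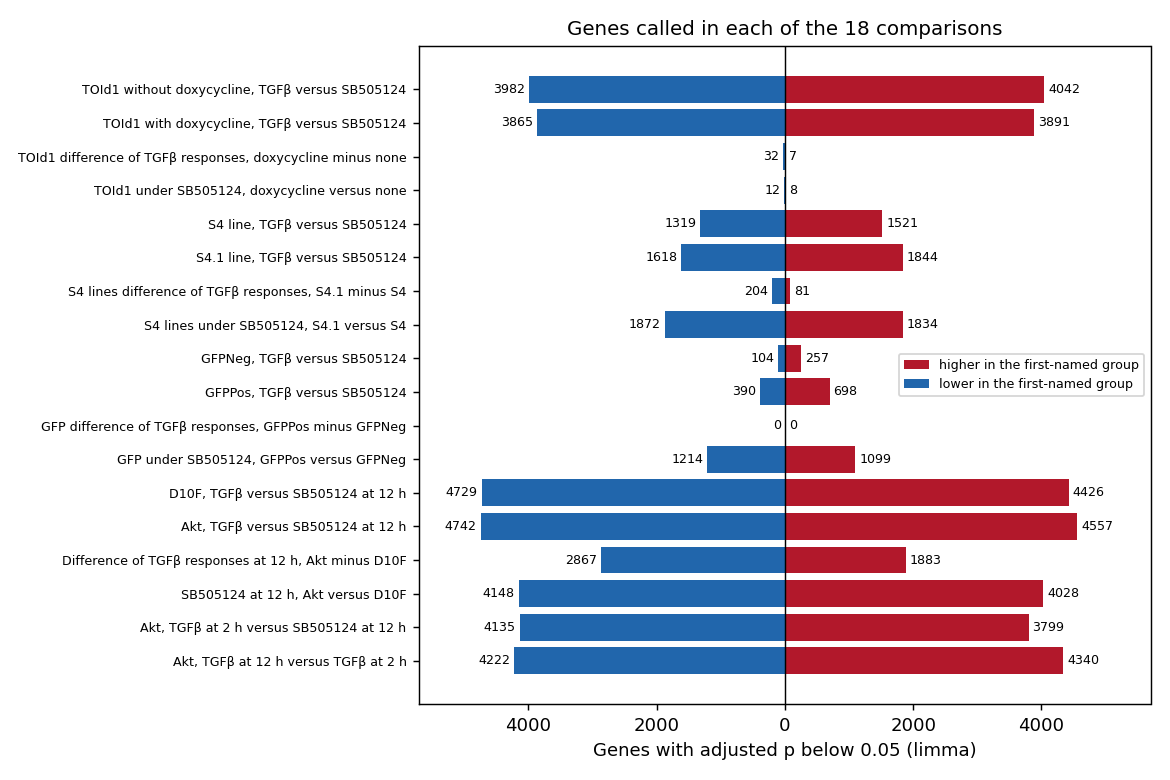
Genes called higher (to the right of 0) and lower (to the left) in each comparison, by limma at a Benjamini-Hochberg adjusted p under 0.05; the x axis counts genes. The counts run from 0 for the difference between the GFP arms to 9299 for the Akt cells at 12 h.

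In TOId1 cells without doxycycline, 24 h of TGFβ lowered the 3 Id genes. Has2, a hyaluronan synthase, rose by 9.70 ± 0.55 (limma, adjusted p = 1.94e-08), the cytokine Il11 by 8.64 ± 0.29, Fam167a by 7.91 ± 0.16 and Wisp1, a secreted matricellular protein, by 7.88 ± 0.18. Genes without a read under SB505124 were the tight junction gene Cldn4, at least 1255-fold higher with TGFβ against a floor of 3 reads over the libraries of the group, Olr1 at least 317-fold, Lrp4 at least 202-fold and Prss46 at least 146-fold. Ccl20, a chemokine, fell the most, with a log2 change of -7.23 ± 0.19 (limma, adjusted p = 3.66e-11). Next came the cytochrome P450 genes Cyp1a1 at -6.42 and Cyp2s1 at -6.35, then Dlk2 at -6.33 ± 0.34, the water channel Aqp5 at -5.71, Cobl at -5.41, Ptprr at -5.36 and Eps8l3 at -5.28. Id1 fell from 1330 and 955 normalized counts to 82.1 and 84.0, a log2 change of -3.75 ± 0.14 (limma, adjusted p = 5.14e-10). Id2 changed by -2.93 ± 0.07 and Id3 by -2.13 ± 0.13. Direct targets of the pathway rose, among them Skil by 2.76 and Smad7 by 2.40, together with the transcription factor genes Snai1 by 4.29 ± 0.33 and Sox4 by 2.44. Klf5 changed by -2.31, the E-cadherin gene Cdh1 by -1.19, and Bcl2l11, which encodes the cell death activator BIM, by 1.11 ± 0.08. The cell cycle inhibitor gene Cdkn1a had a change of -0.11 ± 0.06 (limma, adjusted p = 0.12).

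Gene groups moved with them in these cells. Of the 27 measured TGFβ SMAD targets 22 rose and 2 fell, and adjusted over the list alone 22 rose and 3 fell (camera, adjusted p = 1.2e-08, and adjusted p = 0.0702 with an estimated correlation). Fn1 rose by 5.02, Col7a1 by 4.75 and Ctgf by 4.25. All 33 S phase genes fell, also when adjusted over the list alone, with a median of -1.28 and with Tk1 at -2.63 and E2f2 at -2.08 (camera, adjusted p = 1.58e-14, and adjusted p = 0.151 with an estimated correlation). All 32 mitosis genes fell as well, likewise adjusted over the list alone, with Mybl2 at -2.09, Aurkb at -1.87 and Mki67 at -1.85 (camera, adjusted p = 5.3e-13, and adjusted p = 0.367 with an estimated correlation). Of 32 FOXO targets, 22 rose and 7 fell, and 22 and 9 adjusted over the list alone (camera, adjusted p = 0.00688, and adjusted p = 0.346 with an estimated correlation). Among them Bmf, another cell death activator, rose by 5.63, the ubiquitin ligase gene Fbxo32 by 5.15 and Gadd45a by 4.45, while Sepp1 fell by 3.17. Of 29 genes of the integrated stress and unfolded protein response 24 fell and 5 rose, the same counts as adjusted over the list alone (camera, adjusted p = 3.31e-05, and adjusted p = 0.151 with an estimated correlation). Stc2 changed by -4.99 and the serine synthesis genes Psat1 and Phgdh by -2.24 and -2.21, against 2.87 for Nupr1. Of 23 glutathione and NRF2 target genes 17 fell, again the same count adjusted over the list alone, with the cystine transporter gene Slc7a11 at -2.04 and Gclc, which starts glutathione synthesis, at -2.05 (camera, adjusted p = 9.24e-06, and adjusted p = 0.0702 with an estimated correlation). In all, 8024 of 11918 genes tested were called by limma, 4042 higher and 3982 lower, of which 2394 changed at least 2-fold.

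With doxycycline, TGFβ treatment of the same cells left Id1 high and lowered Id2 and Id3 more. Id1 stood at 7689 and 7230 normalized counts under SB505124 and at 5388 and 6874 with TGFβ, a change of -0.29 ± 0.14 (limma, adjusted p = 0.0835). That value passed the threshold with only the compared groups in the fit (limma, adjusted p = 0.00317) and without replicate 2 of the doxycycline and TGFβ group (limma, adjusted p = 0.0286). Id2 fell by 4.01 ± 0.07 (limma, adjusted p = 3.75e-12) and Id3 by 4.52 ± 0.13 (limma, adjusted p = 7.39e-11). Has2 rose by 10.64 ± 0.55, Il11 by 8.32, Cldn4 by 8.31, Fam167a by 7.94 and Olr1 by 7.94, while Ccl20 changed by -6.43, Cyp1a1 by -6.19, Cyp2s1 by -5.97, the kinase gene Sgk2 by -5.77 ± 0.48 and Eps8l3 by -5.59. Of the 27 SMAD targets 22 rose and 3 fell, and 22 and 4 adjusted over the list alone (camera, adjusted p = 5.49e-09, and adjusted p = 0.0706 with an estimated correlation). All 33 S phase and all 32 mitosis genes fell, also adjusted over the list alone, with medians of -1.15 and -1.55 (camera, adjusted p = 6.02e-15 and 2.41e-15, and adjusted p = 0.124 and 0.349 with an estimated correlation). Limma called 7756 genes, 3891 higher and 3865 lower. Genes higher in both arms numbered 3575, against 1320 if the lists were independent, and 3510 were lower in both, against 1291, while 6 were called in opposite directions.

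The test of the difference between these responses asked which of them doxycycline altered, and the 3 Id genes were among those called. The Id1 response was 3.45 ± 0.20 higher with doxycycline (limma, adjusted p = 1.73e-05), the Id3 response -2.39 ± 0.18 (limma, adjusted p = 0.000126) and the Id2 response -1.08 ± 0.10 (limma, adjusted p = 0.000641). Id1 counts do not separate a doxycycline-induced copy from the endogenous gene. The Id1 difference therefore does not show how the endogenous gene responded to TGFβ. The protease gene Prss23 differed by -1.54 ± 0.14 (limma, adjusted p = 0.000641), Csf2, a myeloid growth factor gene, by -1.78 ± 0.23 (limma, adjusted p = 0.00575) and Macc1 by -1.43 ± 0.18 (limma, adjusted p = 0.00534). Csf2 and Macc1 missed the threshold without replicate 2 of the doxycycline and TGFβ group (limma, adjusted p = 0.0642 and 0.0543). The FOXO target Fbxo32 differed by -1.09 ± 0.18 (limma, adjusted p = 0.0276). It was the 1 called member of its list of 32, where 5 passed when adjusted over the list alone, each lower (camera, adjusted p = 0.000124, and adjusted p = 0.366 with an estimated correlation). Among 32 mitosis genes limma called 0 over all genes and 0 adjusted over the list alone, and edgeR and DESeq2 called 0 each. At an unadjusted p under 0.05, limma found 19 lower, and the list's median was -0.28 (camera, adjusted p = 2.66e-15, and adjusted p = 0.493 with an estimated correlation). Among 30 MYC and ribosome biogenesis genes limma called 0 over all genes and 0 adjusted over the list alone, and edgeR and DESeq2 called 0 each. At an unadjusted p under 0.05, limma found 11 higher, with a list median of 0.18 (camera, adjusted p = 8.84e-12, and adjusted p = 0.0352 with an estimated correlation). The response of Smad7 (0.15 ± 0.10; limma, adjusted p = 0.801) did not pass the test. Limma called 39 genes, 7 higher and 32 lower, with 877 at an unadjusted p under 0.05, while edgeR called 36 and DESeq2 69. The count was 22 with no filter on low counts and ran from 11 to 252 as 1 of the 8 libraries was left out, reaching 252 without replicate 2 and 87 without replicate 1 of the TGFβ group lacking doxycycline. Of those calls 49.2% and 35.6% were higher. The share was 4.17% and 5.56% without replicate 2 and 1 of the doxycycline and SB505124 group, 7.14% without replicate 1 of the doxycycline and TGFβ group and 4.55% with no filter, so the balance of higher and lower genes is not settled.

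Under SB505124, doxycycline itself raised Id1 by 2.73 ± 0.14 (limma, adjusted p = 5.22e-06) and left few other changes. The kidney-type cotransporter gene Slc12a1 rose by 1.28 ± 0.11 (limma, adjusted p = 0.000233), Mpp5 by 0.88 ± 0.07 (limma, adjusted p = 0.00021) and Nebl by 0.95 ± 0.09 (limma, adjusted p = 0.000808). Fibronectin, Fn1, fell by 1.04 ± 0.06 (limma, adjusted p = 8.35e-06), the matrix gene Thbs1 by 1.10 ± 0.09 (limma, adjusted p = 0.000178) and Apob by 0.63 ± 0.07 (limma, adjusted p = 0.00118). Id2 and Id3 had changes of 0.02 ± 0.07 and 0.02 ± 0.13 (limma, adjusted p = 0.958 and 0.985). Among 19 YAP and TEAD targets, 2 fell over all genes and 4 when adjusted over the list alone, with a list median of -0.08 (camera, adjusted p = 0.000476, and adjusted p = 0.398 with an estimated correlation). Limma called 20 genes, 8 higher and 12 lower, with 930 at an unadjusted p under 0.05, while edgeR called 18 and DESeq2 45. With only the compared groups in the fit 5 were called, and Nebl and Thbs1 were not among them (limma, adjusted p = 0.215 and 0.127). No filter gave 8, and the count was 21 without replicate 1 of the SB505124 group lacking doxycycline, 13 without its replicate 2 and 9 without either doxycycline library.

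**Figure D2:**
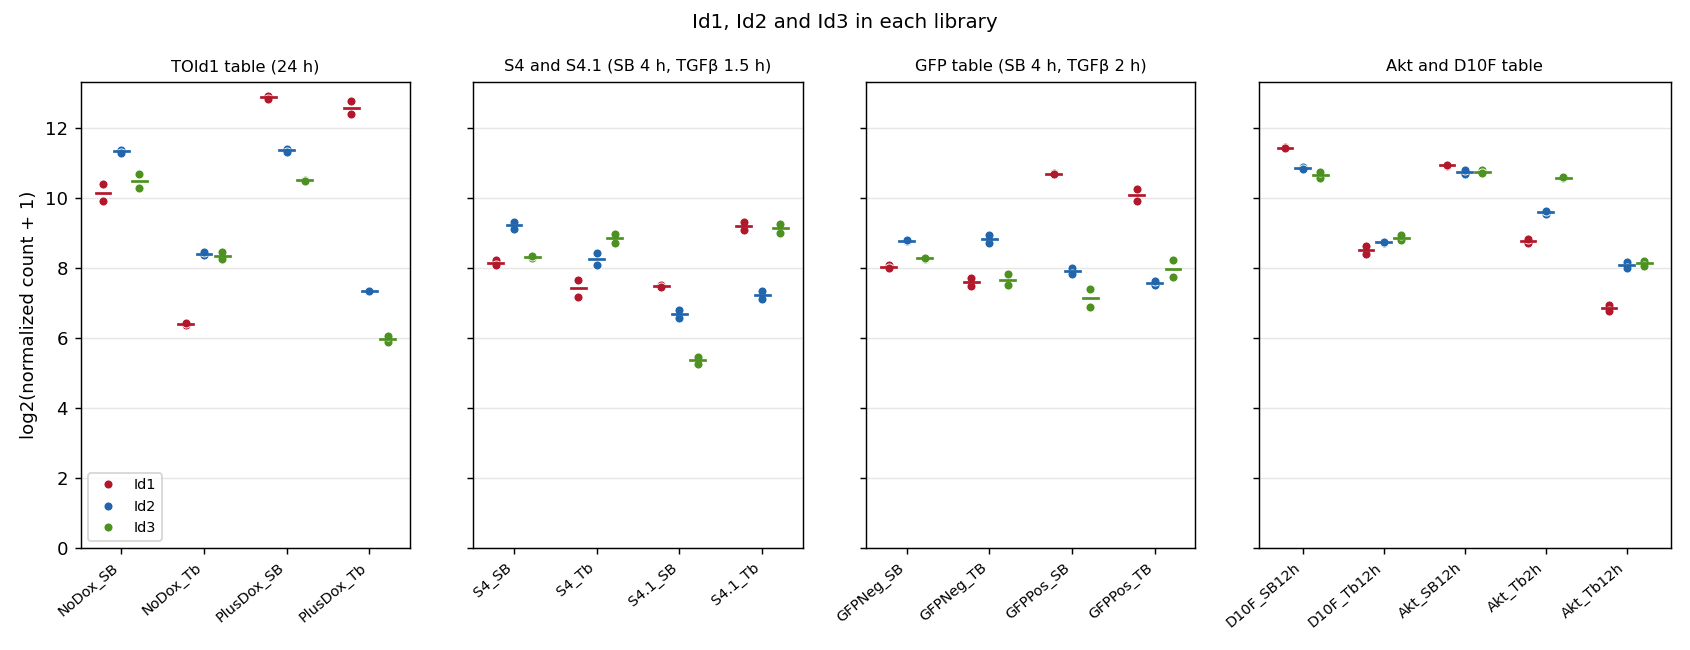
Id1, Id2 and Id3 in every RNA-seq library as log2(normalized count + 1) on the y axis, with 1 dot per library and a line at each group's mean, in 4 panels for the 4 separately normalized tables. Id1 falls from 1330 and 955 to 82.1 and 84.0 normalized counts in TOId1 cells without doxycycline and rises from 181 and 174 to 539.7 and 626 in S4.1 cells.

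In S4 cells, 1.5 h of TGFβ was compared with 4 h of SB505124, so time differs between the groups. Among the largest rises were Cldn4 at 6.22 ± 0.29 (limma, adjusted p = 8.37e-10), Gadd45a at 3.75 ± 0.11, Bhlhe40 at 3.62 ± 0.07, Arid3a at 3.47, Smad7 at 3.44, the AP-1 gene Fosb at 3.29 and Sox9 at 3.01. Snai1, without a read under SB505124, was at least 25.0-fold higher. Ccl20 fell by 3.48 ± 0.18 (limma, adjusted p = 2.75e-09), the chemokine Cxcl5 by 2.68, Hs3st1 by 2.38, Myc by 1.95 ± 0.07, Clec2d by 1.88, Rgs2 by 1.58, the noncoding RNA Dancr by 1.55 and Pim3 by 1.54. Id1 fell by 0.72 ± 0.14 (limma, adjusted p = 0.00253) and Id2 by 0.96 ± 0.14 (limma, adjusted p = 0.000276). Id3 rose by 0.53 ± 0.13 (limma, adjusted p = 0.01), and missed the threshold without replicate 1 or 2 of the SB505124 group or replicate 1 of the TGFβ group (limma, adjusted p = 0.0905, 0.057 and 0.115). Of 24 SMAD targets 18 rose and 1 fell, and 19 and 2 adjusted over the list alone, with Ctgf at 2.91 and Junb at 2.65 (camera, adjusted p = 2.03e-17, and adjusted p = 0.0172 with an estimated correlation). Of 21 immediate early genes 13 rose and 2 fell, and 13 and 3 adjusted over the list alone, with Fos at 2.97 and Jun at 2.08 (camera, adjusted p = 2.45e-06, and adjusted p = 0.079 with an estimated correlation). Of 27 glycolysis and hypoxia genes 14 rose, and adjusted over the list alone 15 rose and 1 fell, with Vegfa at 2.14 and Ddit4 at 2.48 (camera, adjusted p = 3.31e-08, and adjusted p = 0.0518 with an estimated correlation). Of 20 MAPK feedback genes 8 fell and 3 rose, as they did adjusted over the list alone, with the inhibitor genes Spry1 at -1.54 and Dusp6 at -1.02 (camera, adjusted p = 0.0221, and adjusted p = 0.325 with an estimated correlation). Limma called 2840 of 11691 genes, 1521 higher and 1319 lower, so 53.6% were higher, a share of 34.9% after upper-quartile rescaling. Leaving out any 1 of the 4 libraries gave 1214 to 1853 called genes.

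S4.1 cells answered the same treatment with higher Id genes. Id3 rose by 3.77 ± 0.13 (limma, adjusted p = 8.22e-11) and Id1 by 1.70 ± 0.14 (limma, adjusted p = 1.25e-06), from 181 and 174 to 539.7 and 626 normalized counts. Id2 rose by 0.54 ± 0.14 (limma, adjusted p = 0.0123), and missed the threshold with only the compared groups in the fit (limma, adjusted p = 0.0829) or without replicate 1 of the SB505124 or of the TGFβ group (limma, adjusted p = 0.0565 and 0.0927). Cldn4 rose by 3.50 ± 0.29, the AP-1 genes Junb by 3.31 and Fos by 3.28, and Smad7 by 3.10 ± 0.11. Ccl20 fell 17.1-fold. On the log2 scale, the stress genes Chac1 and Trib3 fell by 2.13 and 2.12, Lgsn by 2.07, Clec2d by 2.01 and Myc by 1.84. Of 29 integrated stress genes 24 fell and 1 rose, as they did adjusted over the list alone, with Slc7a11 at -1.92 and Ddit3 at -1.83 (camera, adjusted p = 5.66e-14, and adjusted p = 0.0402 with an estimated correlation). Of 32 mitosis genes 22 fell, and 25 adjusted over the list alone, with Birc5 at -0.74 and Ttk at -0.69 (camera, adjusted p = 8.96e-11, and adjusted p = 0.0341 with an estimated correlation). Of 24 SMAD targets 16 rose and 1 fell, and 16 and 3 adjusted over the list alone (camera, adjusted p = 8.96e-11, and adjusted p = 0.0341 with an estimated correlation). Limma called 3462 genes, 1844 higher and 1618 lower. Leaving out replicate 2 of the SB505124 group gave 1601 and replicate 2 of the TGFβ group 1525, and 1384 were called with only the compared groups in the fit. Between the S4 and S4.1 responses 842 genes were higher in both, against 239.9 if independent, 621 were lower in both, against 182.5, and 46 were opposite.

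Tested directly, the responses of S4.1 and S4 cells differed in the 3 Id genes and in stress genes, among others. The Id3 response was higher in S4.1 by 3.24 ± 0.19 (limma, adjusted p = 2.4e-07), that of Id1 by 2.43 ± 0.20 (limma, adjusted p = 9.76e-06) and that of Id2 by 1.50 ± 0.20 (limma, adjusted p = 0.000736). The DNA repair gene Ung differed by 1.43 ± 0.16 (limma, adjusted p = 0.000193). Chac1 differed by -3.005 ± 0.24 (limma, adjusted p = 6.88e-06), Trib3 by -2.89 ± 0.20 (limma, adjusted p = 1.07e-06), the stress transcription factor gene Atf3 by -1.98 ± 0.20 and the hyaluronan synthase gene Has3 by -2.01 ± 0.31. Trib3 went from 75.1 ± 1.02 (SD, n = 2) to 129 ± 14.4 normalized counts in S4 and from 339.7 ± 16.8 to 77.4 ± 1.17 in S4.1. Among TGFβ targets, Ctgf and Skil responded less in S4.1, with differences of -1.59 for Ctgf and -1.48 ± 0.14 for Skil (limma, adjusted p = 2.5e-05). Smad7 at -0.34 ± 0.15 (limma, adjusted p = 0.252) and Bcl2l11 at -0.01 ± 0.12 (limma, adjusted p = 0.969) did not pass. Of 29 integrated stress genes 20 had a lower response, and 23 adjusted over the list alone, with Herpud1 at -1.98 and Ddit3 at -1.58 (camera, adjusted p = 1.02e-26, and adjusted p = 0.0251 with an estimated correlation). A lower response was seen in 7 of 32 mitosis genes, and 19 adjusted over the list alone, with Top2a at -0.63 and Kif20a at -0.60 (camera, adjusted p = 2.08e-12, and adjusted p = 0.0251 with an estimated correlation). Of 24 SMAD targets 6 had a lower and 2 a higher response, and 10 and 3 adjusted over the list alone (camera, adjusted p = 0.000195, and adjusted p = 0.0727 with an estimated correlation). Limma called 285 genes, 81 higher and 204 lower (28.4% higher, or 39.2% after upper-quartile rescaling), edgeR called 313 and DESeq2 304. The count was 123 with no filter and ran from 92 to 901 with 1 of the 8 libraries left out, at 901 without replicate 1 of the S4.1 SB505124 group, 152 without replicate 1 of the S4.1 TGFβ group and 92 to 165 without any one of the 4 S4 libraries.

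Before TGFβ, S4.1 and S4 cells already differed widely. Under SB505124, S4.1 cells had more of the secreted trefoil factors, with Tff3 7.39 ± 0.18 higher (limma, adjusted p = 7.8e-13), from 16.7 ± 5.24 (SD, n = 2) to 2904 ± 387 normalized counts, and Tff2 5.87 ± 0.30 higher. Nepn was 7.00 ± 0.24 higher, the acute phase gene Lbp 5.97 ± 0.13 and Gulp1 5.68 ± 0.52. Genes without a read in S4.1 were Rps4l, at least 468-fold lower, Gramd1a at least 127-fold, the lipid transporter gene Atp11a at least 111-fold and Zfp334 at least 106-fold. Rps4l is a paralog of Rps4x, so reads of the pair cannot be told apart with certainty. Klhl13 differed by -7.37 ± 0.21 (limma, adjusted p = 3.31e-12). Id3 was lower in S4.1 by a log2 difference of -2.95 ± 0.13 (limma, adjusted p = 3.44e-10), Id2 by -2.52 ± 0.14 (limma, adjusted p = 4.92e-09) and Id1 by -0.65 ± 0.14 (limma, adjusted p = 0.00282). Smad4 had a difference of -0.08 ± 0.10 (limma, adjusted p = 0.599). Mitosis genes were lower in 29 of 32, and 31 adjusted over the list alone, with Ube2c at -1.25 ± 0.08 and Ccnb2 at -1.16 (camera, adjusted p = 1.1e-17, and adjusted p = 0.0243 with an estimated correlation). Of 29 integrated stress genes 18 were higher and 2 lower, and 20 and 2 adjusted over the list alone, with Trib3 at 2.16 and Stc2 at 2.10 (camera, adjusted p = 5.83e-08, and adjusted p = 0.175 with an estimated correlation). Of 21 mesenchymal and matrix genes 12 were lower and 4 higher, and 12 and 5 adjusted over the list alone, with Cald1 at -3.15, Thbs1 at -2.80 and the collagen gene Col3a1 at 3.45 (camera, adjusted p = 0.0144, and adjusted p = 0.267 with an estimated correlation). Limma called 3706 genes, 1834 higher and 1872 lower, of which 846 differed at least 2-fold. Leaving out replicate 1 or 2 of the S4 SB505124 group gave 2395 and 2380.

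GFP-negative cells, compared after 2 h of TGFβ with 4 h of SB505124, raised Snai1 by 4.38 ± 0.34 (limma, adjusted p = 1.45e-05), Has2 by 3.57 ± 0.21 (limma, adjusted p = 1.89e-06), the scavenger receptor gene Olr1 by 3.44, Wisp1 by 3.13, Arid3a by 3.08, Ucn2 by 2.90, Il11 by 2.77 and Cldn4 by 2.63. The heparan sulfate sulfotransferase gene Hs3st1 fell by 2.63 ± 0.14 (limma, adjusted p = 1.33e-06), the chemokine Cxcl1 by 2.13, the homeobox gene En1 by 2.04 ± 0.11, Ccl20 by 1.75, Rgs2 by 1.67, Angptl4 by 1.64 and Cd300lb by 1.47. Id1, Id2 and Id3 had changes of -0.43 ± 0.14, 0.04 ± 0.13 and -0.60 ± 0.21 and did not pass (limma, adjusted p = 0.169, 0.995 and 0.245), although Id3 did with only the compared groups in the fit (limma, adjusted p = 0.00487). In GFP-positive cells, Snai1 rose by 5.37 ± 0.34 (limma, adjusted p = 2.69e-06), Cldn4 by 3.11, Junb by 2.89, Nfatc2 by 2.74 and Smad7 by 2.56. Cxcl1 fell by 2.63 ± 0.13 (limma, adjusted p = 6.18e-07), Hs3st1 by 2.54, Cxcl5 by 2.20, Egr1 by 2.12 and Rnd3 by 1.87. There Id1 fell by 0.61 ± 0.14 and Id3 rose by 0.84 ± 0.21 (limma, adjusted p = 0.0204 and 0.0312). Both missed the threshold by limma with no filter (0.051 and 0.0856), with only the compared groups in the fit (0.0791 and 0.125) and without replicate 1 of the SB505124 group (0.108 and 0.255) or of the TGFβ group (0.16 and 0.22). Of 27 SMAD targets 15 rose and 2 fell in GFP-negative cells, and 17 and 2 adjusted over the list alone, with Ctgf at 2.60 (camera, adjusted p = 2.02e-22, and adjusted p = 0.0746 with an estimated correlation). In GFP-positive cells 14 rose and 2 fell, and 19 and 3 adjusted over the list alone (camera, adjusted p = 8.29e-12, and adjusted p = 0.241 with an estimated correlation). Of 20 NF-kB and cytokine genes 6 fell and 1 rose in GFP-positive cells, the same counts as adjusted over the list alone, with Ccl20 at -2.42 (camera, adjusted p = 0.00753, and adjusted p = 0.276 with an estimated correlation). Limma called 361 of 11885 genes in GFP-negative cells, 257 higher and 104 lower, and 1088 in GFP-positive cells, 698 higher and 390 lower. With only the compared groups in the fit these counts were 657 and 285, and with no filter the second was 461. Leaving out 1 of the 4 libraries, whichever it was, gave 157 to 215 in GFP-negative cells; in GFP-positive cells it gave 279 and 335 without replicate 1 of the SB505124 and TGFβ groups, and 1717 and 2502 without their replicate 2. Both responses shared 202 higher genes, against 15.1 if independent, and 81 lower ones, against 3.41.

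No gene passed the test of the difference between the GFP-positive and GFP-negative responses. Limma called 0 genes, with 2026 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 26. Id3 was 1.44 ± 0.29 higher in its response (limma, adjusted p = 0.229; DESeq2, adjusted p = 0.021), Id1 -0.18 ± 0.19 (limma, adjusted p = 0.635) and Id2 -0.39 ± 0.18 (limma, adjusted p = 0.302). Without replicate 2 of the GFP-positive SB505124 group 475 genes passed, and without replicate 2 of the GFP-positive TGFβ group 896, Id3 among them each time (limma, adjusted p = 0.0167 and 0.0105). In data simulated for this comparison a 1.5-fold difference was recovered in 13.4% of changed genes and a 2-fold difference in 79.1%. There 200 genes were changed, a number on which recovery depends. Each gene had the same dispersion in every simulated group and genes varied independently. The real GFP-positive pairs differed more, with chi-square per degree of freedom of 14.45 and 16.27 against 8.58 and 9.48 in GFP-negative pairs. Those shares may therefore be too high for the real libraries.

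Under SB505124, GFP-positive cells had more eGFP and more Id1. The data were deposited under the name Id1GFP, so both differences may follow from how the cells were made, which the labels do not give. The eGFP sequence was 3.22 ± 0.18 higher (limma, adjusted p = 2.33e-06) and Id1 2.66 ± 0.14 higher (limma, adjusted p = 1.49e-06), from 269 and 251 normalized counts in GFP-negative cells to 1657 and 1641. Id2 was lower by a log2 difference of -0.87 ± 0.13 (limma, adjusted p = 0.00102) and Id3 by -1.13 ± 0.21 (limma, adjusted p = 0.00358). The transferrin gene Trf was 3.71 ± 0.25 higher, Bpifa5 3.10, the complement protease gene C1s1 3.03 and the collagen gene Col12a1 2.94. Tex101 differed by -6.25 ± 0.39 (limma, adjusted p = 3.63e-06), the mast cell tryptase gene Tpsab1 by -5.15, the retinaldehyde dehydrogenase gene Aldh1a3 by -4.82, Rhox5 by -4.49 and the chaperone gene Hspb8 by -4.13. Bcl2l11 was lower, at -0.68 ± 0.11, and Cdkn1a higher, at 0.51 ± 0.09. In the list of ID genes and BMP targets, which holds these 3 Id genes, 5 of 10 were lower and 1 higher, the same counts as adjusted over the list alone, with Atoh8 at -3.79 and Gata2 at -2.38 (camera, adjusted p = 0.0198, and adjusted p = 0.453 with an estimated correlation). Of 10 NOTCH targets 5 were lower, again also adjusted over the list alone, with Jag2 at -3.17 and Notch4 at -2.22 (camera, adjusted p = 0.0149, and adjusted p = 0.498 with an estimated correlation). Limma called 2313 genes, 1099 higher and 1214 lower. Without replicate 1 or 2 of the GFP-negative group it called 938 and 947, and without replicate 1 of the GFP-positive group 1252.

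In D10F cells, 12 h of TGFβ raised Cldn4 by 9.60 ± 0.07 (limma, adjusted p = 8.11e-27), Olr1 by 9.23 ± 0.37, Has2 by 8.62, Il11 by 8.51 ± 0.06, Wisp1 by 8.11, Cd40, a costimulatory receptor gene, by 7.74 and the collagen gene Col5a3 by 7.57. Lce1f had no read under SB505124 and was at least 151-fold higher with TGFβ. Cyp1a1 fell by 6.13 ± 0.21 (limma, adjusted p = 4.75e-16), Aqp5 by 5.34, Cyp2s1 by 5.14, the alarmin gene Il33 by 5.00, Hsd17b14 by 4.94 ± 0.51, Tcf23 and Ptprz1 by 4.88 each and Fgfbp1 by 4.60. Id1 went from 2769 and 2748 normalized counts to 332 and 395 (limma, adjusted p = 7.33e-18), Id2 fell by 2.12 ± 0.06 and Id3 by 1.79 ± 0.07. Of 27 SMAD targets 23 rose and 2 fell, also adjusted over the list alone, with Col7a1 at 6.23 (camera, adjusted p = 1.44e-10, and adjusted p = 0.0363 with an estimated correlation). All 33 S phase genes fell, also adjusted over the list alone, with a median of -0.96 and with Tk1 at -1.94 (camera, adjusted p = 2.55e-12, and adjusted p = 0.0363 with an estimated correlation). Among mitosis genes 30 of 32 fell and 1 rose, the same counts as adjusted over the list alone (camera, adjusted p = 5.98e-11, and adjusted p = 0.139 with an estimated correlation). Of 30 MYC and ribosome biogenesis genes 28 fell and 1 rose, as they did adjusted over the list alone, with the spermidine synthase gene Srm at -1.11 (camera, adjusted p = 1.44e-10, and adjusted p = 0.17 with an estimated correlation). Of 28 glycolysis and hypoxia genes 19 rose and 3 fell, with the same counts adjusted over the list alone and with Vegfa at 4.15 (camera, adjusted p = 0.000356, and adjusted p = 0.284 with an estimated correlation). Limma called 9155 of 12362 genes, 4426 higher and 4729 lower. The protocol text of the labels names the AKT inhibitor MK2206 at 2.5 µM for every sample, D10F included. The arms of the table are named Akt and D10F, however, and the Akt libraries at 2 h are described as Akti. All Akt columns, at 2 h and 12 h, are headed Akti, and the D10F columns are not. Whether the D10F cells had MK2206 is therefore unclear.

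In Akt cells at the same time the cell cycle genes were again lower with TGFβ. All 33 S phase genes fell, also adjusted over the list alone, with a median of -2.69 and with Cdc6 at -4.71, Ccne2 at -4.50, Tk1 at -3.76 and Ccne1 at -3.73 (camera, adjusted p = 5.85e-19, and adjusted p = 0.0273 with an estimated correlation). Of 32 mitosis genes 31 fell and 1 rose, the same counts as adjusted over the list alone, with Mybl2 at -3.79, Aurkb at -2.78 and the cyclin gene Ccna2 at -2.74 (camera, adjusted p = 1.59e-15, and adjusted p = 0.0683 with an estimated correlation). All 35 sterol and fatty acid synthesis genes fell, also adjusted over the list alone, with the elongase gene Elovl6 at -2.12 (camera, adjusted p = 8.21e-12, and adjusted p = 0.121 with an estimated correlation). Of 27 SMAD targets 22 rose and 2 fell, and adjusted over the list alone the counts were the same (camera, adjusted p = 7.77e-10, and adjusted p = 0.0394 with an estimated correlation). Cldn4 rose by 8.63 ± 0.07 (limma, adjusted p = 8.5e-26), Has2 by 8.56, Il11 by 7.99, Hr by 7.58, Cd40 by 6.99 and the adhesion gene Mcam by 6.80. Col5a3 and Wfdc8 had no read under SB505124 and were at least 145-fold and at least 86.2-fold higher with TGFβ. Ccl20 fell by 6.47 ± 0.60 (limma, adjusted p = 5.21e-09), Cyp2s1 by 5.50, Cyp1a1 by 5.38 ± 0.21, Aldh1a1 and its paralog Aldh1a7 by 5.34 and 5.28, Fgfbp1 by 5.34, Efemp1 by 5.32 and Slfn9 by 5.30. Close relatives can share reads of Aldh1a7 and Slfn9. Id1 fell by 4.08 ± 0.08 (limma, adjusted p = 2.75e-20), from 1911 and 1962 to 120.2 and 107 normalized counts, Id2 by 2.66 and Id3 by 2.61. Bcl2l11 rose by 1.85 ± 0.05 and Cdkn1a by 0.47 ± 0.03. Limma called 9299 genes, 4557 higher and 4742 lower. Against D10F, 3633 genes were higher in both responses, with 1632 if independent, 3845 were lower in both, with 1814, and 337 were opposite.

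The difference between the Akt and D10F responses was tested as well. Among the lists named for this difference, S phase genes had the lowest median relative response, -1.37. All 33 were lower, also adjusted over the list alone, with examples in Cdc6 at -3.70 ± 0.10 (limma, adjusted p = 8e-16), Ccne2 at -3.26 ± 0.17 and Ccne1 at -2.79 (camera, adjusted p = 9.46e-36, and adjusted p = 0.00605 with an estimated correlation). The DNA repair and checkpoint genes Exo1 and Clspn differed by -3.04 and -2.85, and Slfn9 by -3.76 ± 0.20. Of 32 mitosis genes 31 had a lower response, also adjusted over the list alone, with Mybl2 at -2.22 (camera, adjusted p = 2e-25, and adjusted p = 0.0312 with an estimated correlation). Of 35 sterol and fatty acid synthesis genes 34 had a lower response, also adjusted over the list alone, with Insig1 at -1.40 and Dhcr7 at -1.27 (camera, adjusted p = 1.51e-25, and adjusted p = 0.0312 with an estimated correlation). Of 29 integrated stress genes 20 had a higher and 6 a lower response, and 21 and 6 adjusted over the list alone, with Chac1 at 1.74 and Mthfd2 at 1.42 (camera, adjusted p = 7.09e-09, and adjusted p = 0.0428 with an estimated correlation). Id1 differed by -1.16 ± 0.11 (limma, adjusted p = 5.27e-08), Id3 by -0.82 ± 0.09, Id2 by -0.53 ± 0.09, Cdh1 by -0.54 ± 0.05 and Bcl2l11 by 1.20 ± 0.07 (limma, adjusted p = 2.39e-11). The proteases Mep1a and Mmp10 responded 2.30 ± 0.25 and 2.22 ± 0.28 higher in Akt cells. Limma called 4750 genes, 1883 higher and 2867 lower, so 39.6% were higher, a share of 27.9% after upper-quartile rescaling.

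With TGFβ signalling blocked, Akt and D10F cells differed in lipid synthesis and mitosis. Of 35 sterol and fatty acid synthesis genes 34 were higher in Akt cells, also adjusted over the list alone, with a median of 2.04 and with the sterol sensor partner Insig1 at 3.50 ± 0.03 (limma, adjusted p = 5.49e-24), Mvd at 3.37 and Fdps at 3.26 (camera, adjusted p = 1.39e-29, and adjusted p = 0.0285 with an estimated correlation). All 32 mitosis genes were lower, also adjusted over the list alone, with a median of -1.64 and with Cdc20 at -2.20 and Plk1 at -2.12 (camera, adjusted p = 2.37e-25, and adjusted p = 0.0285 with an estimated correlation). Of 33 S phase genes 32 were lower, as they were adjusted over the list alone, with Tk1 at -1.32 (camera, adjusted p = 4.8e-12, and adjusted p = 0.0285 with an estimated correlation). Of 28 lysosome and autophagy genes 25 were higher, also adjusted over the list alone, with Atg9b at 1.41 and Wipi1 at 1.09 (camera, adjusted p = 1.63e-12, and adjusted p = 0.111 with an estimated correlation). Of 34 FOXO targets 24 were higher and 7 lower, the same counts as adjusted over the list alone, with Fbxo32 at 2.10 and Gadd45a at 1.88 (camera, adjusted p = 1.73e-05, and adjusted p = 0.231 with an estimated correlation). The phosphatidate phosphatase gene Lpin1 was 4.13 ± 0.10 higher and Angpt2 3.28 ± 0.16 higher. The mucin gene Muc5ac differed by -4.45 ± 0.47, Cyp2c65 by -3.27, Il33 by -2.97, the growth factor gene Ereg by -2.64 and Apoc2 by -2.49. Id1 was lower in Akt cells, at -0.51 ± 0.08 (limma, adjusted p = 6.96e-06). Limma called 8176 genes, 4028 higher and 4148 lower.

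The Akt cells were also sampled after 2 h of TGFβ, against the SB505124 libraries of 12 h, so time differs between these groups too. Cldn4 rose by 7.19 ± 0.07 (limma, adjusted p = 2.73e-24), Has2 by 5.86 ± 0.46, Snai1 by 5.84 and Fam167a by 5.00, and Ccl20 fell by 5.07 ± 0.60, Hs3st1 by 3.05, Ccne2 by 2.88, Clec2d by 2.81 ± 0.13 and Angptl4 by 2.79. Id1 fell by 2.16 ± 0.08 (limma, adjusted p = 3.36e-15), Id2 by 1.14 and Myc by 1.49, while Bcl2l11 rose by 1.95 ± 0.05. All 33 S phase genes fell, also adjusted over the list alone, with Cdc6 at -2.67 (camera, adjusted p = 2.83e-18, and adjusted p = 0.023 with an estimated correlation). Mitosis genes went the other way, with 20 of 32 higher and 4 lower, the same counts as adjusted over the list alone, Ccnb2 at 1.57 and Cenpa at 1.48 (camera, adjusted p = 3.6e-06, and adjusted p = 0.187 with an estimated correlation). Of the 27 SMAD targets 22 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 2.34e-12, and adjusted p = 0.023 with an estimated correlation). Limma called 7934 genes, 3799 higher and 4135 lower.

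From 2 h to 12 h of TGFβ in Akt cells, Il11 rose by 5.28 ± 0.06 (limma, adjusted p = 1.07e-22), Lce1g by 5.36 ± 0.32, Col5a3 by 5.09, the neuron navigator gene Nav2 by 4.49 and the lubricin gene Prg4 by 4.35. Akt cells had no SB505124 libraries at 2 h. Effects of longer TGFβ and of longer culture therefore cannot be told apart in this comparison. Cyp2s1 fell by 5.31 ± 0.21 (limma, adjusted p = 1.55e-14), Fgf1 by 5.09, Cyp1a1 by 5.08 ± 0.21, the aminopeptidase gene Anpep by 4.16 and Prl2c2 by 4.13, with Lce1g and Prl2c2 from gene families whose members can share reads. Id3 fell by 2.45 ± 0.07, Id1 by 1.92 ± 0.08 and Id2 by 1.51 ± 0.06, while Myc rose by 1.31 ± 0.03 (limma, adjusted p = 8.33e-18). All 32 mitosis genes fell, also adjusted over the list alone, with a median of -2.38 and with Ccna2 at -2.71, Kif11 at -2.58 and Mki67 at -2.57 (camera, adjusted p = 6.65e-26, and adjusted p = 0.0324 with an estimated correlation). All 33 S phase genes fell, again also adjusted over the list alone, with Tk1 at -2.67 (camera, adjusted p = 1.47e-18, and adjusted p = 0.0298 with an estimated correlation). Of 23 glutathione and NRF2 targets 18 fell and 1 rose, and 19 and 1 adjusted over the list alone, with Nqo1 at -2.39 (camera, adjusted p = 5.45e-08, and adjusted p = 0.238 with an estimated correlation). Limma called 8562 genes, 4340 higher and 4222 lower, so 50.7% were higher, a share of 40.6% after upper-quartile rescaling. Bcl2l11 had a change of -0.10 ± 0.05 (limma, adjusted p = 0.0732), which passed after upper-quartile rescaling, with only the compared groups in the fit and in edgeR (adjusted p = 0.00343 and 0.0127 by limma and 0.024 by edgeR).

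**Figure D3:**
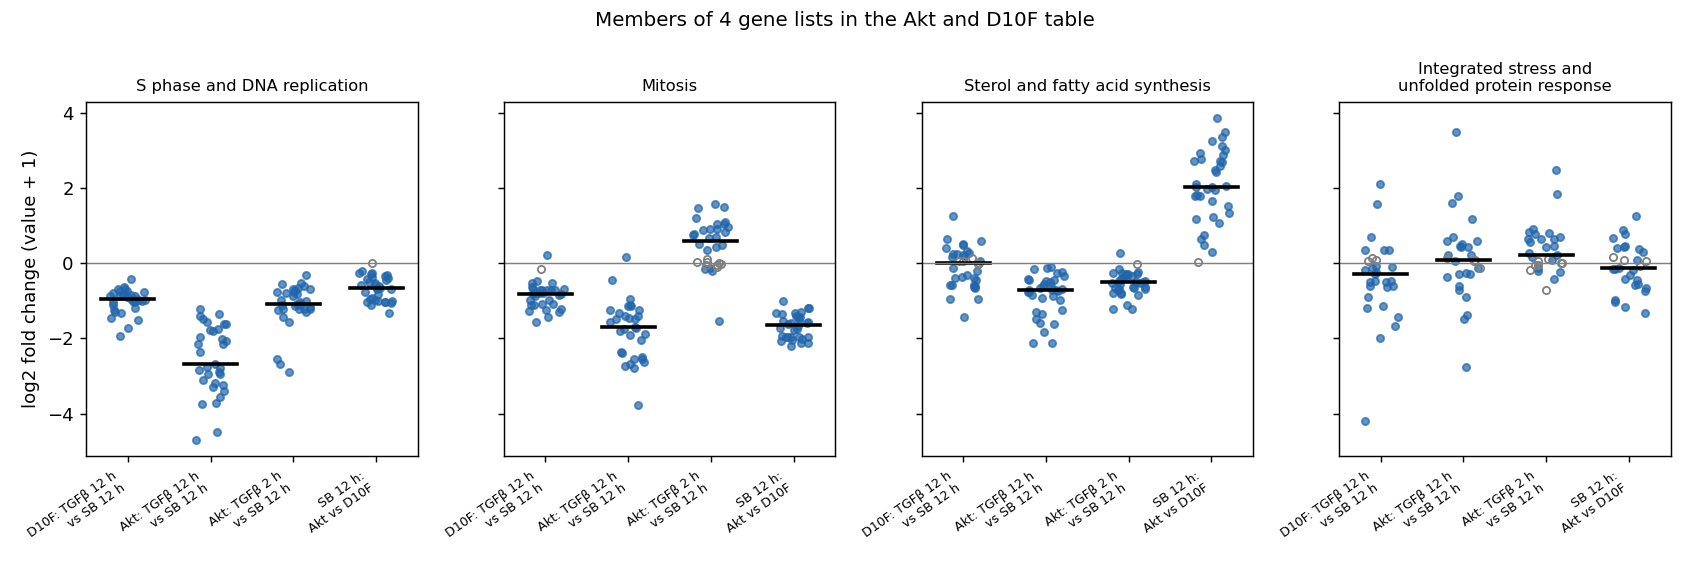
Members of 4 gene lists in 4 comparisons of the Akt table, as log2 fold changes on the y axis; filled blue dots passed the limma test, open grey dots did not, and a black line marks the list's median. The S phase list has medians of -0.96 in D10F cells and -2.69 in Akt cells at 12 h, and the sterol list has a median of 2.04 between Akt and D10F cells under SB505124.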

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

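The tests of the explanations below were chosen after the results were seen, except the pair on genes low in S4.1, while the differences between responses were planned. The rule for single outlying samples needs groups of at least 4 and was not applied, so the results listed by arm are tested differences between the TGFβ responses of 2 arms, by limma with Benjamini-Hochberg adjustment, while the genes low in S4.1 come from the contrast of S4.1 and S4 under SB505124.

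With and without doxycycline, 39 genes differed in their response in TOId1 cells. Id1 differed by 3.45, with any induced copy counted together with the endogenous gene. Chrna1 differed by 0.69, Mrc1 by 0.68, S100a7a by 0.68 and Areg by 0.62. The last 4 missed the threshold with no filter (limma, adjusted p = 0.103, 0.0581, 0.0814 and 0.0905) and with several single libraries left out. Prss23 differed by -1.54, Csf2 by -1.78, Macc1 by -1.43, Id3 by -2.39 and Id2 by -1.08. Csf2 and Macc1 missed the threshold without replicate 2 of the doxycycline and TGFβ group (limma, adjusted p = 0.0642 and 0.0543). Cldn4 had a fitted difference of -2.52, which depends on the pseudocount because its group without doxycycline had no read under SB505124. It did not pass by edgeR or DESeq2 (adjusted p = 0.68 and 0.693) or without replicate 1 or 2 of the doxycycline and TGFβ group (limma, adjusted p = 0.0588 and 0.0543). List medians were 0.18 for MYC and ribosome biogenesis and -0.28 for mitosis.

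Id2 and Id3 fell further under TGFβ when doxycycline held Id1 high. A single unusual library was excluded for Id3, since its difference was -2.19 at its nearest to 0 with 1 of the 8 libraries left out. That test does not cover Id2. Doxycycline itself remains open, because no doxycycline-treated cells without the inducible Id1 were sampled. GFP-positive cells, with more Id1 and no doxycycline, had an Id3 difference of -1.13 from GFP-negative cells under SB505124 but of 0.31 ± 0.21 under TGFβ (limma, adjusted p = 0.303). Their Id2 was lower under both, by 0.87 under SB505124 and by 1.26 under TGFβ on the log2 scale. With doxycycline under SB505124, Id3 changed by 0.02 ± 0.13 although Id1 rose there too, and Id2 did not pass the test there. A lowering of Id2 or Id3 by Id1 is left open as well.

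Between S4.1 and S4 cells, 285 genes differed in their response. Id3 differed by 3.24, Id1 by 2.43, Id2 by 1.50, Ung by 1.43 and Smtnl2 by 1.38, the last missing the threshold with no filter and without replicate 1 of the S4 SB505124 group (limma, adjusted p = 0.0559 and 0.0574). Chac1 differed by -3.005, Trib3 by -2.89, Has3 by -2.01, Atf3 by -1.98 and Skil by -1.48. Cldn4 differed by -2.73 and missed the threshold with no filter (limma, adjusted p = 0.0515). Snai1 had a fitted difference of -3.48, which depends on the pseudocount since S4 had no read under SB505124, and missed the threshold without replicate 1 of the S4.1 TGFβ group (limma, adjusted p = 0.0609). List medians were 0.64 for ID genes and BMP targets, -0.25 for SMAD targets, -0.37 for mitosis and -0.77 for the integrated stress response. Of the 9 ID genes and BMP targets, 4 had a higher response, the 3 Id genes among them, and 4 adjusted over the list alone (camera, adjusted p = 3.19e-08, and adjusted p = 0.0727 with an estimated correlation).

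The Id genes rose in S4.1 cells relative to their change in S4 cells. An exchange of the SB505124 and TGFβ labels in S4.1 was excluded, as Smad7, Skil and Ccl20 each moved as in S4, by 0.85 or more on the log2 scale. A single library was excluded for Id1, by a difference of 2.19 or more with any 1 of the 8 left out. That test does not cover Id2 or Id3. A return from a low level under SB505124 to the level of S4 was excluded for Id1, which stood 1.77 above S4 under TGFβ. Id2 stood 2.52 below S4 under SB505124 and 1.03 below it under TGFβ. A full return was therefore excluded for Id2, but a partial one was not. For Id3 the values a full return needs were there, with a difference of 0.29. A difference in biology between the cells stays open and was not tested.

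Under SB505124, 67 genes were at least 16-fold lower in S4.1 than in S4, and 16 were at least 16-fold higher. A loss of chromosome segments holding neighbouring genes was excluded as the whole cause, since 2.98% of the 67 genes, Evc and its neighbour Evc2, lay beside another such gene and the 67 were spread over 19 chromosomes. A fault of the SB505124 libraries was excluded by the separate TGFβ libraries, where the median difference of these genes was -4.94 and 67 of 67 were lower. A difference between the cells in origin or in silencing of these genes was not tested, and the labels do not give how S4.1 was derived.

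Between Akt and D10F cells at 12 h, 4750 genes differed in their response. Mep1a differed by 2.30, Mmp10 by 2.22, Cdk5r2 by 2.14, Cyp2c65 by 2.08 and Muc5ac by 2.07, and the last 3 did not pass by edgeR (adjusted p = 0.212, 0.182 and 0.188). Cdk5r2 and Muc5ac also missed the threshold with no filter (limma, adjusted p = 0.0524 and 0.0807). Under SB505124 Muc5ac and Cyp2c65 were already lower in Akt than in D10F cells, by 4.445 and 3.269 on the log2 scale. Their responses therefore started from unlike levels. Slfn9 differed by -3.76, Cdc6 by -3.70, Ccne2 by -3.26, Exo1 by -3.04 and Clspn by -2.85. Among the fixed genes Id1 differed by -1.16, Id2 by -0.53, Id3 by -0.82, Smad7 by 0.43, Skil by -0.29, Cdh1 by -0.54, Cdkn1a by 0.30, Bcl2l11 by 1.20 and Myc by 0.33. Smad4 differed by -0.26 and missed the threshold without replicate 1 of the D10F SB505124 group or replicate 2 of the Akt SB505124 group (limma, adjusted p = 0.0583 and 0.0565). Sox4 differed by -0.18 and missed it without replicate 1 of the D10F TGFβ group or replicate 2 of the Akt TGFβ group (limma, adjusted p = 0.0599 and 0.059). List medians were -1.37 for S phase, -0.85 for mitosis, -0.77 for sterol synthesis, 0.48 for the integrated stress response and 0.18 for p53 targets. Sterol synthesis genes were mostly higher, and S phase and mitosis genes mostly lower, in Akt cells under SB505124. These list responses too started from unlike levels. Of 21 p53 targets 11 had a higher and 1 a lower response, the same counts as adjusted over the list alone (camera, adjusted p = 0.000252, and adjusted p = 0.153 with an estimated correlation).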

How the results depend on the processing

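The alternatives for counts and list tests were planned, while for single genes the fits to only the compared groups, edgeR, DESeq2 and the left-out libraries were added after the results were seen. No paired analysis was possible because the columns carry no replicate number, so the planned replicate block was not run. Of 518 gene results, with 5446 values under the alternatives, none reversed, and 66 uncalled values changed sign and stayed uncalled. A gene result is a gene in 1 comparison, so the same gene can count several times. The side of the threshold was the same for 516 gene results with a pseudocount of 5, 511 after upper-quartile rescaling, 508 by edgeR and 497 with no filter. DESeq2 kept 499, with 9 lost and 3 gained, and only the compared groups kept 431, with 22 lost and 6 gained, among the gene results to which these applied. With a library left out 2263 values kept their side, 115 lost a call and 26 gained 1.

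The count of genes whose response differed with doxycycline, 39 by limma, was 22 with no filter, 69 by DESeq2 and 11 to 252 with 1 library left out. Doxycycline under SB505124, with 20, gave 8 with no filter, 45 by DESeq2, 5 with only the compared groups and 9 to 21 with a library left out. Left-out libraries gave 1214 to 1853 genes against 2840 in S4, 1525 to 4035 against 3462 in S4.1 (1384 with only the compared groups), 92 to 901 against 285 for their difference (123 with no filter) and 2380 to 3471 against 3706 between them under SB505124. GFP-negative cells, with 361, gave 157 to 215, and 657 with only the compared groups. GFP-positive cells, with 1088, gave 279 to 2502, with 285 for only the compared groups and 461 with no filter. The difference between the GFP arms, with 0 by limma and 2026 at an unadjusted p under 0.05, gave 0 to 896, with 26 by DESeq2 and 0 by edgeR. The contrast of these arms under SB505124, with 2313, gave 938 to 2028. With a library left out the share called higher moved by more than 10 points for the difference with doxycycline (from 4.17% to 49.2%), for the S4.1 and S4 difference (45.2% without replicate 1 of the S4.1 SB505124 group, against 28.4%), for GFP-positive cells (76.8% and 50.0% without replicate 2 of the SB505124 or TGFβ group, against 64.2%) and between the GFP arms under SB505124 (36.5% without replicate 2 of the GFP-positive group, against 47.5%). The cause of these shifts was not tested. Other counts of the planned comparisons stayed within 1.5 times. Of 522 list tests camera called 164, of which 23 passed with an estimated correlation, while no filter gave 169 of 590 and upper-quartile rescaling 171.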

Other observations

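The 3 comparisons between arms under TGFβ were chosen after the results were seen, while the prediction for genes shared between doxycycline and GFP was written before its result. Under TGFβ, doxycycline left Id1 6.18 ± 0.14 higher in TOId1 cells (limma, adjusted p = 5.71e-10) and the cotransporter gene Slc12a1 0.91 ± 0.11 higher. Id3 was lower by -2.37 ± 0.13 (limma, adjusted p = 2.07e-06), Id2 by -1.06 ± 0.07, Prss23 by -2.32 ± 0.10, Macc1 by -1.85 ± 0.13, Mfap3l by -1.71 ± 0.11 and Csf2 by -1.58 ± 0.17. Of 32 FOXO targets 7 were lower, and 11 adjusted over the list alone, with the ubiquitin ligase gene Fbxo32 at -1.28 and the cell death activator Bmf at -1.13 (camera, adjusted p = 0.000284, and adjusted p = 0.524 with an estimated correlation). Bcl2l11 was at -0.46 ± 0.08 (limma, adjusted p = 0.00969) and missed the threshold with only the compared groups in the fit and without either doxycycline library (limma, adjusted p = 0.0571, 0.0845 and 0.14). Among 32 mitosis genes 10 were lower, and adjusted over the list alone 25 were lower and 1 higher, with Top2a at -0.41 (camera, adjusted p = 4.18e-11, and adjusted p = 0.567 with an estimated correlation). Limma called 648 genes, 240 higher and 408 lower. The share called higher was 19.1% with only the compared groups, 50.2% without replicate 2 of the TGFβ group lacking doxycycline and 20.8% without replicate 2 of the doxycycline group. The count was 131 for only the compared groups, 291 with no filter. It was 424 without replicate 1 and 3661 without replicate 2 of the TGFβ group lacking doxycycline, and 81 and 77 without replicate 1 and 2 of the doxycycline group.

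Under TGFβ, S4.1 cells kept the trefoil factors far above S4, with Tff3 8.00 ± 0.18 higher (limma, adjusted p = 2.48e-13) and Tff2 6.60 ± 0.30, and Nepn, Lbp and the tight junction gene Cldn3 were 6.46, 5.77 and 5.35 higher. Klhl13 differed by -8.57 ± 0.21 and Crip1 by -7.76 ± 0.25, and Rps4l, Gramd1a and Auts2, with no read in S4.1, were at least 465-fold, at least 148-fold and at least 118-fold lower. Id1 was 1.77 ± 0.14 higher (limma, adjusted p = 2.11e-07), Id2 differed by -1.03 and Id3 by 0.29 ± 0.13 (limma, adjusted p = 0.0976). Of 32 mitosis genes 31 were lower, also adjusted over the list alone, with a median of -1.12 (camera, adjusted p = 2e-23, and adjusted p = 0.014 with an estimated correlation). Limma called 4572 genes, 2246 higher and 2326 lower. GFP-positive cells under TGFβ differed from GFP-negative ones in 2565 genes, 1246 higher and 1319 lower, with eGFP 3.67 ± 0.18 higher, Id1 2.48 ± 0.14 higher and Tex101 at -6.89 ± 0.39. The last count was 931 and 879 without replicate 1 and 2 of the GFP-negative TGFβ group and 1287 without replicate 1 of the GFP-positive one.

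A hypothesis was that genes moved by doxycycline under TGFβ, apart from Id1, differ in the same direction between GFP-positive and GFP-negative cells under SB505124, where Id1 is also higher. The result was negative, and the genes leaned the opposite way. The contrasts differ in treatment (TGFβ against SB505124), in time (24 h against 4 h) and in cells. They therefore cannot decide whether more Id1 acts alike in both kinds of cells. The genes were not scored between the GFP arms under TGFβ. Over 642 such genes the median difference, signed by the direction with doxycycline, was -0.10, and 249 genes, or 38.8%, went the same way. Of 10000 random lists matched on expression, with a median of -0.007, 0 lay lower. Random lists treat genes as independent, so the place among them does not measure how firm the opposite lean is.

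The GFP table also lists eGFP and a human SMAD4 sequence, named h_SMAD4, and the other tables list neither. Normalized counts of eGFP were 158 to 191 in GFP-negative and 1288 to 2143 in GFP-positive libraries, and those of h_SMAD4 240 to 317 and 149 to 217. Under TGFβ h_SMAD4 differed by -0.73 ± 0.17 between GFP-positive and GFP-negative cells (limma, adjusted p = 0.0122, and 0.125 without replicate 1 of the GFP-negative TGFβ group), and under SB505124 by -0.46 ± 0.17 (limma, adjusted p = 0.0785). The mouse gene Smad4 had normalized counts of 255 to 371 there and 372 to 449 in the S4 table. It had 2443 to 3422 in the TOId1 table and 2844 to 6812 in the Akt table. The tables were normalized separately and differ in depth. The largest Smad4 share in a GFP or S4 library was 450 of 14240956 recovered reads, in replicate 1 of the S4 SB505124 group. The smallest in a TOId1 or Akt library was 2553 of 31257393, in replicate 1 of the doxycycline and TGFβ group. These shares argue against depth as the source of the gap, and its cause was not tested. Whether reads of a human SMAD4 were counted as Smad4 in the tables without h_SMAD4 cannot be told.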
